A study of Mus musculus with 4 samples.

How the data were processed

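RNA sequencing of total RNA was carried out by the study's authors on primary mouse Leydig cells, labelled 6-month-old mouse, with 2 samples that received Negative siRNA and 2 that received Trps1 siRNA. Per the labels, RNA was extracted with a commercial kit (E.Z.N.A.) and libraries followed the usual Illumina procedure. The authors deposited a table of raw read counts per gene for the 4 samples, and the submitters' processing notes name HISAT2 and featureCounts with the mouse genome GRCm38 (mm10), without versions. Read length, strandedness, the treatment of reads that map to several places and any filtering of ribosomal RNA reads are not given in the sources used here. The counts were whole numbers for 55812 features, of which 55401 carried Ensembl identifiers and 411 were features without an Ensembl identifier, named and numbered by the authors. The authors also deposited a table of 780 genes with their own comparison. Its mean signal per group equalled the mean of the counts divided by median-of-ratios size factors, with a largest relative difference of 4.8e-10, as recomputed from the deposited values. Its log2 fold changes were, in the authors' deposited table, the log2 ratio of those means, and the test behind the authors' p-values is not given in the sources used here.

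Samples were grouped by the titles in the labels. Gene symbols, positions, exon lengths and transcript sequences came from GENCODE M21 for GRCm38, matched on the Ensembl identifier, and 55141 features had a symbol. The 260 Ensembl features not in M21 and the authors' own features kept their identifiers. Library totals were 20116799, 25852898, 17844125 and 21597187 counts, which limited the precision for genes with few counts. Before averaging, replicates were compared with a chi-square statistic of their counts. It averaged 7.60 per gene between the Negative siRNA samples and 4.61 between the Trps1 siRNA samples, so both pairs differed by more than sampling noise. The Pearson correlation of log2 values across genes was 0.995 and 0.996, where genes are not independent replicates.

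The comparison used edgeR 4.0.16 (R 4.3.3) on the deposited counts, with TMM normalisation, filterByExpr with a minimum count of 10, glmQLFit with robust=TRUE and glmQLFTest. The design held the group only, coded as Trps1 siRNA minus Negative siRNA, with 2 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. Standard errors of log2 fold changes were the fold change divided by the square root of the F statistic. CPM values were computed with TMM-scaled library sizes, and the biological coefficient of variation was 0.0664. Before the data were examined, 36 gene lists were fixed, and 33 of them had at least 3 tested members. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 3 and a preset correlation of 0.01, adjusted over the 33 lists. No list call held with an estimated correlation, for which camera uses the 2 residual degrees of freedom. Even adult Leydig markers, with an estimated correlation of -0.072, then had a camera p of 0.0412 and an adjusted p of 0.715. The loss of calls therefore does not separate correlated lists from others. The estimated correlations themselves differed, from 0.923 for ribosomal proteins and 0.683 for interferon response to 0.012 for cholesterol synthesis and uptake. For lists with a high estimate, the preset correlation of 0.01 gives p-values that may be far too small.

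The rule for named genes, fixed at the same time, took Trps1 and Ccnd1, the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups, and up to 4 members of each list with the smallest p. Genes known only by a clone name, a pseudogene name or an identifier were counted and not named. Further members of lists, such as Star, Insl3, Vcam1, Cyp11a1, Nr5a1, Tspo, Akr1c14, Sqle, Irf7, Lyz2, Csf1r, Crim1, Egln3 and Cd4, were chosen after their values were seen. Of the 147 genes the rule took, 48 share exon sequence with another annotated gene. Those that overlap a gene on the opposite strand are uncertain where counting did not use strand. Those that overlap one on the same strand, such as Fdps, Fgfr2 and Tgtp1, are uncertain either way.

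Alternatives planned beforehand were RLE size factors, library totals alone, no low-count filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma voom, glmQLFit without robust estimation, the replicate number as a block, each sample left out in turn, and for lists an estimated correlation and fry. Offsets for GC content and exon length, by loess with a span of 0.3 in each library, were added after seeing the data. The fit was tested on simulated counts for 14477 genes, of which 200 were changed. It called 80% of genes lowered and 92% of genes raised by 1 on the log2 scale, 54% and 56% of those lowered and raised by 0.5, and 4 of 14277 unchanged genes. In simulated data the list test gave a p of 6.76e-09 for a shifted list and a p under 0.05 for 3 of 50 unshifted lists. The simulated genes varied independently, so this rate does not cover lists whose members vary together.

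A search of 3' UTRs for short sequences was added after the main results were seen, with Python 3.11.15 and numpy 2.4.6. For each of 10399 genes with a mean of at least 5 CPM and an annotated 3' UTR of at least 50 bases, the longest 3' UTR was searched for all 7-base sequences (heptamers). Log2 fold changes, limited to 2 in size, were regressed on the presence of each of 15561 heptamers held by at least 100 genes, with UTR length and base content as covariates, and p-values were Benjamini-Hochberg adjusted. Genes are not independent replicates in this search. With fold changes permuted over genes no heptamer was called, and a heptamer planted with a shift of -0.1 ranked first. Permuting removes variation that genes share, so it does not give the rate of calls between real samples. Between the 2 Trps1 siRNA samples the lowest and highest z were -5.09 and 6.68.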

Results

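Gene expression was measured by RNA sequencing in primary Leydig cells, the testosterone-producing cells that lie between the seminiferous tubules of the testis. The labels give the stage as 6-month-old mouse, and the cells received either a small interfering RNA (siRNA) against Trps1 or a negative control siRNA. Trps1 encodes a GATA-type zinc finger protein that represses transcription. Each group held 2 samples, called samples 1 and 2 of Negative siRNA and samples 1 and 2 of Trps1 siRNA. The libraries held 20116799 and 25852898 counted reads in the Negative siRNA samples and 17844125 and 21597187 in the Trps1 siRNA samples. In every library Aldh1a1 was the most abundant gene, with 1.43% to 1.52% of the counts, and transcripts of the mitochondrial genome made up 0.915% to 1.12%. The labels do not say whether the samples of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

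The design implied a single comparison, Trps1 siRNA against Negative siRNA. It asks what changes in the transcriptome when Trps1 is lowered, and whether Ccnd1, which the study names as a target of Trps1, and genes of proliferation change with it. With Trps1 siRNA, Trps1 was lowered to 67.1% of its control level and Ccnd1, which encodes the G1 cyclin D1, to 71.9%. In steroid hormone synthesis 10 of 19 genes rose and 2 fell, led by Cyp17a1 with a 6.5-fold rise, and in cholesterol synthesis and uptake 11 of 24 rose and 1 fell. Of interferon-stimulated genes, macrophage markers and cytosolic ribosomal protein genes, 16 of 26, 8 of 18 and 20 of 42 fell, and the camera calls of all these lists were lost with an estimated correlation (adjusted p = 0.715 with an estimated correlation). That form of the test has 2 residual degrees of freedom, so the loss alone does not separate correlated lists from others. The estimated correlation was 0.683, 0.361 and 0.923 for the interferon, macrophage and ribosomal lists, with unadjusted camera p-values of 0.232, 0.237 and 0.346. It was 0.055 and 0.012 for steroidogenesis and cholesterol, with 0.0757 and 0.0713. The calls at the preset correlation of 0.01 are thus less certain for the lists that fell. Ccnd1 and Cdk6 were the 2 of 15 genes of the G1 list that fell, and most genes of DNA replication and mitosis did not pass the test.

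The targeted gene is given first, in each sample. Trps1 (ENSMUSG00000038679, protein coding, chromosome 15, 50654752 to 50890463, minus strand, GRCm38) had 38.1 and 42.2 CPM (read counts scaled to library size) with Negative siRNA and 23.5 and 30.1 CPM with Trps1 siRNA, from 765, 1080, 420 and 655 reads. Its log2 fold change was -0.58 ± 0.10 (standard error), with an adjusted p of 0.000351 in edgeR's quasi-likelihood test, and both Trps1 siRNA samples lay below both control samples. Ccnd1 (ENSMUSG00000070348, protein coding, chromosome 7, 144929931 to 144939925, minus strand) had 83.8 and 79.5 CPM with Negative siRNA and 62.7 and 54.8 CPM with Trps1 siRNA. Its log2 fold change was -0.48 ± 0.07 (edgeR adjusted p = 5.33e-05), again without overlap between the groups. The authors' deposited table gives -0.58 for Trps1 and -0.48 for Ccnd1, with adjusted p-values of 0.0297 and 3.09e-05. The 3' UTR of Ccnd1 holds the bases AGTTGAA in exon 5 (chromosome 7, 144931473 to 144931479). Among genes whose best match to a longer 8-base sequence was these 7 bases, 8.9% of 816 were called lower, against 6.9% of 7164 genes without a match. An annotated gene on the opposite strand, LTO1, shares exon sequence with Ccnd1, and no source used here says whether counting used strand.

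**Figure D1:**
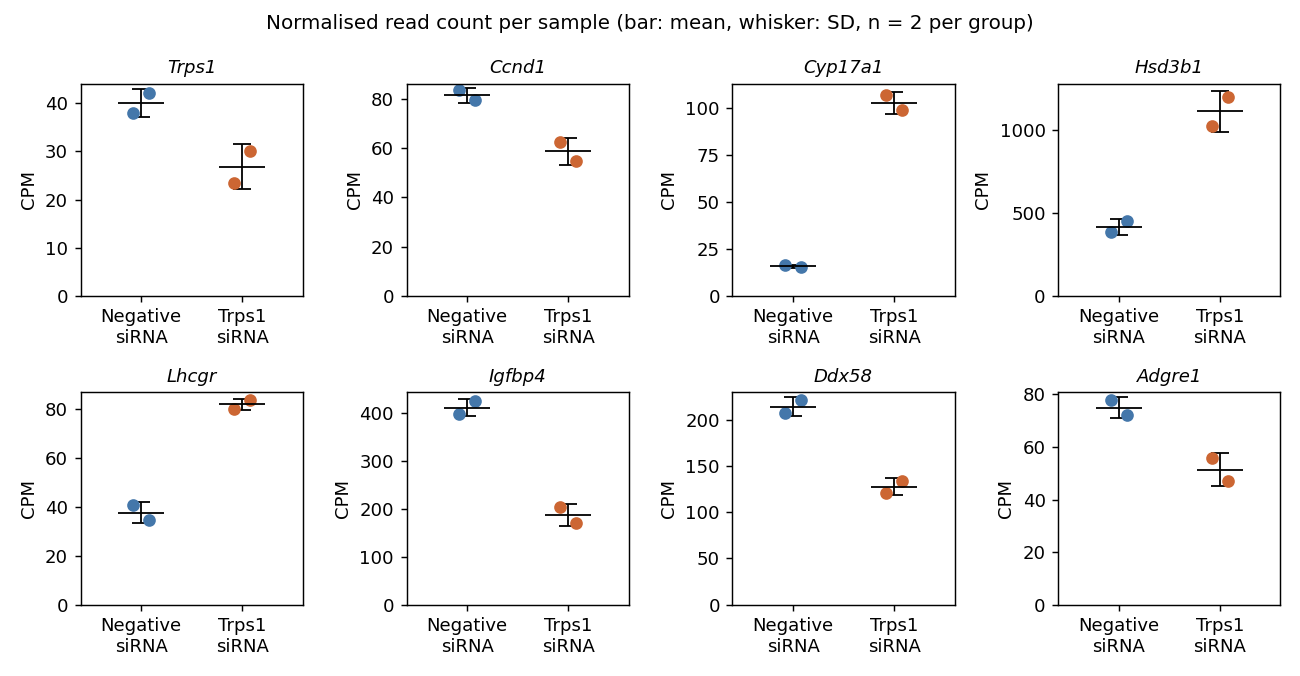
Normalised read count (CPM, vertical axes from 0) of 8 genes in the 4 samples, with the mean and SD of the 2 samples of each group. Trps1, Ccnd1, Igfbp4, Ddx58 and Adgre1 lay lower in both Trps1 siRNA samples, while Cyp17a1, Hsd3b1 and Lhcgr lay higher, with means of 15.9 and 103 CPM for Cyp17a1.

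Of 14701 genes tested, 1652 changed (edgeR, Benjamini-Hochberg adjusted p under 0.05), of which 770 rose and 882 fell. Most changes were small. The median fold of the genes that rose was 1.29 and that of the genes that fell was 0.787. At least a 2-fold change was seen in 109 genes, 79 of them higher and 30 lower. In all 1652 genes the 2 groups did not overlap, which held for 52.2% of all tested genes and holds for 33.3% by chance. Leaving out sample 2 of Trps1 siRNA lowered the count to 871 genes, with 62 at 2-fold or more, and DESeq2 called 914 genes, with 53 at 2-fold or more. Among the 10759 genes with a mean of at least 5 CPM, 42 changed by 2-fold or more. The authors' deposited table lists 780 genes, 355 higher and 425 lower, and 776 of them were called here, all in the same direction.

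The largest rise was that of Cyp17a1, the enzyme that makes androgen precursors from progestins, from 15.9 ± 0.87 to 103 ± 5.66 CPM (SD, n = 2 per group; log2 fold change 2.70 ± 0.08, edgeR adjusted p = 4.04e-18). Sv2c, a synaptic vesicle protein, rose 4.98-fold although its 3' UTR holds GAGTTGAA, and Pgbd5, a gene derived from a transposase, rose 3.65-fold, with CGGAGAA in its 3' UTR. Hsd3b1, which converts pregnenolone to progesterone, rose from 416 ± 46.7 to 1110 ± 124 CPM (SD, n = 2 per group), a 2.67-fold change with an edgeR adjusted p of 1.19e-08. The other 8 genes with the largest rises were Txndc2, Fam222a, Dnah2, Vstm2b, Hephl1, Chrna4, Vstm5 and Espn, with rises of 2.42-fold to 2.88-fold from control means of 2.84 to 11.2 CPM. Dnah2 and Vstm2b share exon sequence with an annotated gene on the opposite strand and are uncertain for that reason.

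Of the 12 genes with the largest falls, the 3 with the highest control levels were Igfbp4, Ergic1 and Nomo1. Igfbp4, a secreted protein that binds insulin-like growth factors, fell to 0.454 of its control level, from 412 ± 18.4 to 187 ± 23.2 CPM (SD, n = 2 per group; log2 fold change -1.14 ± 0.07, edgeR adjusted p = 1.67e-10). Ergic1, a membrane protein of the compartment between endoplasmic reticulum and Golgi, fell from 313 ± 2.08 to 155 ± 1.63 CPM, and Nomo1, a membrane protein of the endoplasmic reticulum, from 135 ± 2.06 to 66.0 ± 3.36 CPM (SD, n = 2 per group). The other 9 genes of this group were Fam107a, Kcnk3, Aif1, Angel1, Rtn1, Tmem178, Tgtp1, Cdo1 and Ms4a6b, which fell to between 0.400 and 0.508 of the control. Fam107a had the largest log2 fold change, -1.32 ± 0.19 (edgeR adjusted p = 3.01e-05). Kcnk3 encodes an acid-sensitive potassium channel, Aif1 a calcium-binding protein of macrophages, and Cdo1 the enzyme that oxidises cysteine. The 3' UTRs of Ergic1, Nomo1, Angel1 and Ms4a6b hold the bases GAGTTGAA, as did 321 searched genes, of which 23.4% were called lower, and that of Igfbp4 holds GAGTTGA without the last A, as in 572 genes, of which 15.2% were called lower. Tgtp1, one of a family of near-identical GTPase genes, could share reads with its copies, and Kcnk3, Ergic1 and Ms4a6b share exon sequence with a gene on the opposite strand.

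Of 19 tested members of the steroidogenesis list, 10 rose, 2 fell and 7 did not pass the test, and adjusted over the list alone 10 rose and 3 fell. The median log2 fold change was 0.39 (camera adjusted p = 7.19e-05, adjusted p = 0.715 with an estimated correlation). Besides Cyp17a1 and Hsd3b1, the receptor for luteinising hormone, Lhcgr, rose 2.18-fold from 37.6 to 81.7 CPM, and the 3' UTR of Lhcgr holds GAGTTGA. So do those of Hsd17b3 and Hsd17b7, which also rose, and that of Fdx1, which did not pass the test, holds GAGTTGAA. Fdxr, which passes electrons to the mitochondrial steroid hydroxylases, rose by 0.67 ± 0.06 on the log2 scale, and Cyp11a1, which cleaves the cholesterol side chain, by 0.49 ± 0.06 (edgeR adjusted p = 1.67e-08 and 1.36e-06). The transcription factor Nr5a1 rose 1.34-fold. The members that fell were Tspo, a cholesterol-binding protein of the outer mitochondrial membrane, to 0.855 of the control, and Akr1c14, which reduces androgens, to 0.800. Star, which carries cholesterol into mitochondria, had a log2 fold change of -0.09 ± 0.06 and did not pass the test. Hsd3b1 and Hsd3b6 are near-identical copies, so the split of reads between them is uncertain.

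The adult Leydig markers share Cyp17a1, Hsd3b1, Lhcgr, Hsd17b3, Cyp11a1, Hsd3b6, Nr5a1 and Star with the steroidogenesis list, so their result largely repeats it. Outside that list only Sult1e1 rose, and Prlr, Ptgds, Insl3, Vcam1 and Hsd11b1 did not pass the test. Of all 14 adult Leydig markers 8 rose, none fell and 6 did not pass the test, and adjusted over the list alone 9 rose. Their median log2 fold change was 0.43 (camera adjusted p = 7.19e-05, adjusted p = 0.715 with an estimated correlation). Sult1e1, an estrogen sulfotransferase, rose 2.37-fold from 410 to 971 CPM. Insl3, the peptide hormone made by Leydig cells, had a log2 fold change of 0.02 ± 0.06, and Vcam1 one of -0.07 ± 0.05, neither past the test. Of 24 genes of cholesterol synthesis and uptake, 11 rose, 1 fell and 12 did not pass the test, and 13 rose adjusted over the list alone. Their median was 0.17 (camera adjusted p = 0.00168, adjusted p = 0.715 with an estimated correlation). Fdps rose 1.79-fold, Dhcr7, which makes cholesterol in the final step of its synthesis, 1.37-fold and Insig1 1.36-fold, whereas Sqle, an epoxidase of the same synthesis, fell to 0.821 of the control. Fdps, with means of 10.9 and 19.5 CPM, shares exon sequence with an annotated gene on the same strand and is uncertain for that reason. The 3' UTR of Insig1 holds CGGAGAA and that of Sqle AGTTGAA. Over the same samples the summed CPM of 18 macrophage markers was 3104 and 3045 with Negative siRNA and 2610 and 2097 with Trps1 siRNA, while the steroidogenesis list summed to 6303, 6628, 8617 and 9162 CPM in the same order.

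Of 26 tested interferon-stimulated genes, 16 fell, none rose and 10 did not pass the test, and adjusted over the list alone 21 fell. The median log2 fold change was -0.33 (camera adjusted p = 2.43e-09, adjusted p = 0.715 with an estimated correlation of 0.683). Cxcl10, a chemokine that attracts T cells, fell to 0.530 of the control (log2 fold change -0.92 ± 0.10, edgeR adjusted p = 7.03e-07). Ddx58, which encodes the RNA sensor RIG-I, fell from 214 ± 10.1 to 128 ± 9.12 CPM (SD, n = 2 per group; log2 fold change -0.75 ± 0.06, edgeR adjusted p = 5.15e-09), and its 3' UTR holds GAGTTGA, as does that of Ifit2, which fell by 0.72 on the log2 scale. The transcription factor Irf7 fell by 0.33 on the log2 scale. The list summed to 5053 and 5529 CPM with Negative siRNA and to 4129 and 4548 CPM with Trps1 siRNA, and macrophage markers to 3104, 3045, 2610 and 2097 CPM, so that sample 2 of Trps1 siRNA had more interferon and fewer macrophage counts than sample 1.

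Macrophage markers fell in 8 of 18 genes, with none higher and 10 that did not pass the test, and adjusted over the list alone 10 fell. Their median log2 fold change was -0.32 (camera adjusted p = 2.53e-04, adjusted p = 0.715 with an estimated correlation of 0.361). Without sample 1 of Trps1 siRNA the median was -0.49. Adgre1, the macrophage surface protein F4/80, fell to 0.684 of the control (log2 fold change -0.55 ± 0.08, edgeR adjusted p = 2.84e-05), and its 3' UTR holds GAGTTGA. Cd68, a lysosomal protein of macrophages, fell to 0.732 and Tyrobp to 0.708. The most abundant marker, the lysozyme Lyz2, fell from 1362 to 1098 CPM, and Csf1r, at 229 and 186 CPM, did not pass the test. For other cell types, edgeR, DESeq2 and voom called 0 of 11 endothelial markers, with 1 at an unadjusted p under 0.05, and 1 of 7 Sertoli markers rose, Gata1 (1.33-fold). Of 4 spermatogonia and spermatocyte markers, Kit and Zbtb16 rose (1.30-fold and 1.25-fold), both also expressed outside germ cells, and the 3' UTR of Zbtb16 holds CGGAGAA. The calls of Gata1, Zbtb16 and Mylk were each lost in at least 1 fit that left out a sample. Of 6 peritubular myoid and smooth muscle markers, Acta2 and Myl9 fell to 0.620 and 0.622 of the control and Mylk rose 1.20-fold. The camera adjusted p was 0.967 for endothelial, 0.853 for Sertoli, 0.390 for spermatogonia and spermatocyte, and 0.0602 for smooth muscle markers. Of the spermatid and lymphocyte markers, 2 genes and 1 gene were tested, and edgeR, DESeq2 and voom called 0 of each. The lymphocyte gene, Cd4, had a log2 fold change of -0.88, past edgeR's test adjusted over the list alone, and no erythroid marker passed the expression filter.

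All 42 tested cytosolic ribosomal protein genes had a negative log2 fold change, 20 fell past the test and 22 did not pass it, and adjusted over the list alone 34 fell. The median log2 fold change was -0.19 (camera adjusted p = 2.43e-09, adjusted p = 0.715 with an estimated correlation of 0.923). Without sample 2 of Trps1 siRNA the median was -0.12. Rplp1 fell to 0.772 of the control, from 915 to 706 CPM, and Rps3 to 0.786 (edgeR adjusted p = 1.70e-04 and 4.39e-04). The list summed to 22830 and 23230 CPM with Negative siRNA and to 21000 and 19090 CPM with Trps1 siRNA, the lower value being in the sample with the fewest macrophage counts (2097 CPM). Ribosomal protein genes have many pseudogene copies, with which the counting could have split reads.

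For proliferation, 2 of 15 genes of the G1 list fell, Ccnd1 and Cdk6, a kinase partner of cyclin D1, and 13 did not pass the test, the same counts as adjusted over the list alone. Cdk6 fell to 0.733 of the control (log2 fold change -0.45 ± 0.13, edgeR adjusted p = 0.0211), and its 3' UTR holds AGTTGAA. In the same list the 3' UTR of E2f3 holds GAGTTGAA and that of Ccnd2 AGTTGAA. Their log2 fold changes were -0.109 and 0.073, neither past the test. The list's median log2 fold change was 0.07, its mean was -0.004, and camera gave an adjusted p of 0.801. The median lay between 0.023 and 0.081 with a sample left out, lowest without sample 2 of Trps1 siRNA and at 0.027 without sample 1 of either group. Of 37 DNA replication genes, 1 fell, Mcm5, a subunit of the replicative helicase, to 0.823 of the control, and 36 did not pass the test, as also adjusted over the list alone. The call of Cdk6 was lost with DESeq2 (adjusted p = 0.138) and without sample 2 of Negative siRNA or of Trps1 siRNA, and that of Mcm5 without sample 1 of Negative siRNA or sample 2 of Trps1 siRNA. The median of the DNA replication list was -0.08, and the camera adjusted p of 0.04999 lay at the threshold (adjusted p = 0.715 with an estimated correlation). Of 32 mitotic genes edgeR, DESeq2 and voom each called 0, and adjusted over the list alone edgeR also called 0, with 5 at an unadjusted p under 0.05. The median of the mitosis list was -0.05 (-0.112 without sample 2 and -0.027 without sample 1 of Negative siRNA), and the log2 fold change was -0.14 ± 0.06 for Top2a and -0.29 ± 0.11 for Plk1 (camera adjusted p for the list = 0.170). Of 7 CDK inhibitors the 3 tools called 0, with 2 at an unadjusted p under 0.05, and the log2 fold change of Cdkn1b was 0.23 ± 0.09 (camera adjusted p for the list = 0.886). Of 21 p53 targets, Eda2r and Phlda3 rose (1.76-fold and 1.25-fold) and 19 did not pass the test (camera adjusted p = 0.163), and both calls were lost without sample 2 of Trps1 siRNA.

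**Figure D2:**
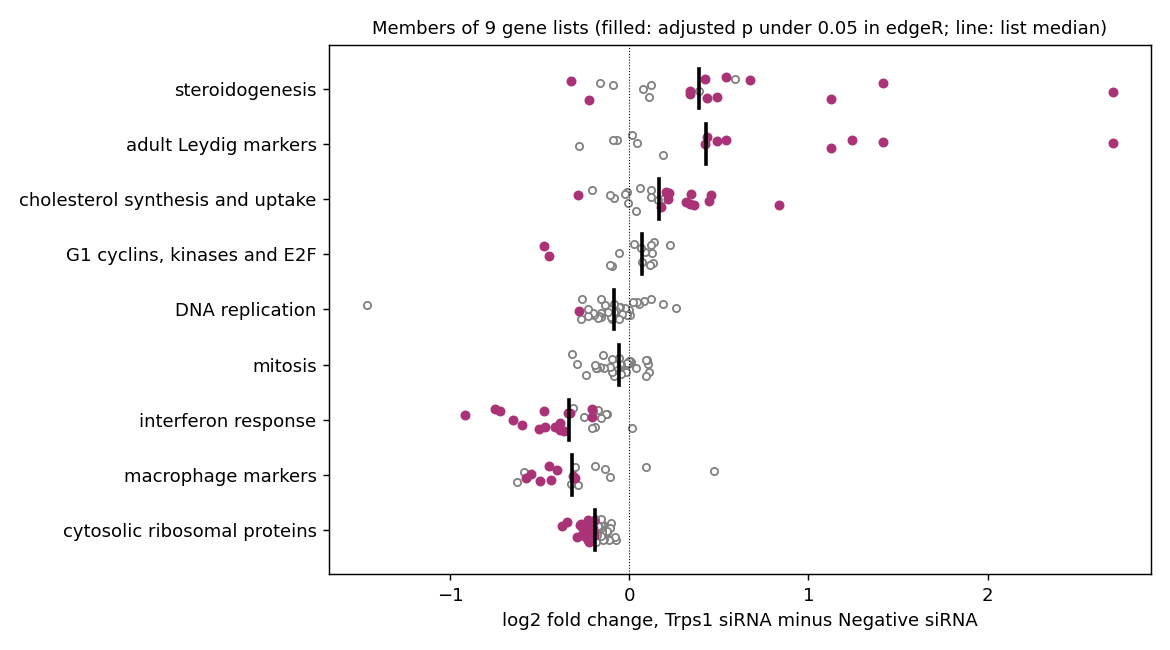
Log2 fold change (horizontal axis, Trps1 siRNA minus Negative siRNA) of each tested member of gene lists named on the vertical axis, filled where edgeR's adjusted p was under 0.05, with a line at the list's median. Members of the interferon, macrophage and ribosomal protein lists lay mostly below 0, with medians of -0.33, -0.32 and -0.19, and steroidogenesis had a median of 0.39.

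Further lists lay at the threshold of camera, each with an adjusted p of 0.04999. Of 21 YAP/TEAD targets, Igfbp3, Axl, Crim1 and Ccn2 fell, Nt5e rose and 16 did not pass the test (adjusted p = 0.715 with an estimated correlation). Of 22 immediate early genes, Ier2, Klf2, Dusp1 and Ier3 fell and 18 did not pass the test (adjusted p = 0.715 with an estimated correlation). Dusp1 shares exon sequence with Ergic1, which lies on the opposite strand and also fell, and is uncertain for that reason. Of 18 genes of glycolysis and hypoxia, Vegfa, Egln3, Eno1 and Bnip3 rose, Adm fell and 13 did not pass the test (adjusted p = 0.851 with an estimated correlation of 0.614). The glycolysis and hypoxia list summed to 9945 and 11600 CPM with Negative siRNA and 11870 and 11680 CPM with Trps1 siRNA, and its median of 0.16 was 0.02 without sample 1 and 0.27 without sample 2 of Negative siRNA. The median of the immediate early list, -0.07, was -0.20 without sample 2 of Trps1 siRNA, and -0.14 and -0.12 without samples 1 and 2 of Negative siRNA. Adjusted over the list alone, the counts were 1 higher and 4 lower for YAP/TEAD targets, 4 lower for immediate early genes, and 6 higher and 2 lower for glycolysis and hypoxia. The calls of Igfbp3, Axl, Ccn2, Ier2, Klf2, Dusp1, Ier3, Eno1 and Bnip3 were each lost in at least 1 fit that left out a sample. Each of these lists, and DNA replication, passed camera in 1 of 4 fits that left out a sample. The 3' UTR of Ier2 holds GAGTTGAA and CGGAGAA, that of Ccn2 AGTTGAA and that of Crim1 CGGAGAA, and macrophage markers summed to 3104 and 3045 CPM with Negative siRNA and 2610 and 2097 CPM with Trps1 siRNA.

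The remaining lists did not pass camera. Genes that changed in both directions were found in the extracellular matrix list, where 6 of 27 rose, among them the collagen cross-linking enzyme Lox (1.49-fold), and 5 fell, among them Thbs1 (0.722 of the control), with a camera adjusted p of 0.855. Of 17 TGF-beta targets, 4 fell, with Tgfbi at 0.583 of the control and GAGTTGAA in its 3' UTR, and none rose (camera adjusted p = 0.195). Of 12 Leydig stem and progenitor markers, 1 rose, Cd34, and 3 fell, among them Ly6a and Eng (camera adjusted p = 0.430). Of 16 ATF4 targets, 5 rose and 2 fell (camera adjusted p = 0.0746), of 23 growth factors and receptors 3 rose and 4 fell (0.855), and of 20 apoptosis regulators 3 rose and 2 fell (0.353). Of 17 NF-kB and inflammatory genes, Cxcl1 rose and Ccl2 and Ccl7 fell (camera adjusted p = 0.311), and of 16 ER chaperones Sdf2l1 and Hsp90b1 fell (0.212). Of 13 NRF2 targets, 3 rose, led by Srxn1 at 1.33-fold (camera adjusted p = 0.311), and of 16 GATA factors and NuRD subunits Gatad2b rose (0.195). Of 12 Wnt genes, Sfrp2 rose and Ccnd1 and Axin2 fell (camera adjusted p = 0.732). edgeR called 0 of 8 epithelial-mesenchymal transition genes, 0 of 7 hedgehog genes, 0 of 11 skeletal and cartilage genes and 0 of 10 mitochondrially encoded genes, with camera adjusted p-values of 0.855, 0.801, 0.869 and 0.311. At an unadjusted p under 0.05 edgeR gave 2, 1, 2 and 1 genes of these lists, and DESeq2 and voom each called 1 gene of the first list and 0 of the others. The 3' UTRs of Gatad2b, which rose, and of Cxcl1 and Cd34 hold GAGTTGA, CGGAGAA and CGGAGAA, and that of Hsp90b1 holds AGTTGAA. Each call of Eng, Cxcl1, Ccl7, Axin2, Gatad2b, Sdf2l1 and Hsp90b1 was lost in at least 1 fit that left out a sample.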

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

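The offsets for GC content and exon length were chosen after seeing the data, and the other alternatives were planned. Trps1 and Ccnd1 kept their direction and passed the test in every alternative run, with log2 fold changes from -0.775 to -0.417 and from -0.575 to -0.382. No gene of the 1652 called changed sign under any alternative in which it was run. DESeq2 called 914 genes, 403 higher and 511 lower, with 53 at 2-fold or more, and 897 of them were among the 1652. The cause was not tested. With a mean of at least 5 CPM 42 genes reached 2-fold, where fewer genes were tested (10759). Leaving out 1 sample, which leaves a lone sample assumed to vary like the other group, gave 871 to 1675 genes changed, 395 to 748 higher, 476 to 927 lower and 62 to 133 at 2-fold or more. The lowest counts came without sample 2 of Trps1 siRNA. The GC and length offsets gave 1666 genes. The replicate number as a block gave 2285 genes, although deviations from the group means correlated at 0.017 between samples of the same number, so the block removed degrees of freedom without a shared structure shown. The other 2 splits of the 4 samples each gave 0 genes with edgeR, DESeq2 and voom (151 and 112 at an unadjusted p under 0.05 in edgeR), and 3 splits are too few for a share under 0.05.

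The number of lists that moved, 10 as reported, was 0 with an estimated correlation, 1 with fry, 6 with RLE size factors, with library totals alone and with the replicate block, and 6 to 9 with a sample left out, of which 6 to 8 were among the 10. The DNA replication median was -0.083 with an estimated correlation (camera adjusted p = 0.715) and with fry, -0.084 with RLE, -0.071 with library totals, -0.079 with the block, and -0.147 to -0.057 with a sample left out, and of the fits that left out a sample it passed without sample 1 of Trps1 siRNA. Steroidogenesis, at 0.390, was not past the threshold with an estimated correlation (camera adjusted p = 0.715) or with fry (0.0776). The cause was not tested. At this depth and with 2 samples per group, 54% of genes simulated at a log2 fold change of -0.5 were called, and the part owed to depth was not separated.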

Other observations

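The lists in this paragraph and the next were chosen after all gene values had been seen, when some members had already been noticed as changed, so they are not independent evidence. Of the tests further below, those of the Leydig cell share, of sites in steroidogenic genes and of the Ccnd1 site were chosen after the results they measure were seen. The tests within groups, in Trps1 transcripts, and of the interferon members were written once the leading sequences and list medians were known. Of 19 tested SRF and actin cytoskeleton targets, 10 fell, 0 rose and 9 did not pass the test, with a median log2 fold change of -0.20 (camera adjusted p = 7.7e-07, adjusted p = 0.246 with an estimated correlation). Srf itself fell to 0.579 of the control, the actin-bundling Palld to 0.622 and the focal adhesion gene Zyx to 0.787. The 3' UTR of Srf holds GAGTTGA, and that of Palld holds GAGTTGA and AGTTGAA at separate places. Peritubular myoid and smooth muscle markers, of which Myl9 is also in this list, summed to 170.1 and 174.8 CPM with Negative siRNA and 148.5 and 148.1 CPM with Trps1 siRNA, and Acta2 and Myl9 fell to 0.620 and 0.622 of the control. Of 25 genes of fatty acid oxidation and lipid droplets, 11 rose, 0 fell and 14 did not pass the test, with a median of 0.20 (camera adjusted p = 3.22e-05, adjusted p = 0.246 with an estimated correlation). The lipid droplet gene Plin1 rose 2.10-fold, the receptor Ppara 1.77-fold and the electron transfer gene Etfdh 1.31-fold.

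Of 14 genes of antigen presentation by MHC class I, 8 fell and 6 did not pass the test, among the former Psmb8 at 0.726 and H2-T23 at 0.781 of the control (camera adjusted p for the list = 0.000548, adjusted p = 0.629 with an estimated correlation). Of 18 genes listed as having 5' TOP mRNAs, translation factors and others, all had negative log2 fold changes. Of these 5 fell, among them Eif3f at 0.803 of the control (camera adjusted p = 0.00084, adjusted p = 0.629 with an estimated correlation). Rack1 and Fau, also among the 5, encode parts of the ribosome, so this list is not separate from the ribosomal protein genes. Of 20 lysosomal genes 6 fell, with Lipa at 0.812 (camera adjusted p = 0.0213, adjusted p = 0.629 with an estimated correlation). Macrophage markers, which fell in the same samples, summed to 3104 and 3045 CPM with Negative siRNA and 2610 and 2097 CPM with Trps1 siRNA. Lists of the circadian clock, proteasome, cAMP and LH signalling, oxidative phosphorylation and mitochondrial ribosomal proteins did not pass camera (adjusted p = 0.254, 0.254, 0.239, 0.0742 and 0.390). For cytosolic ribosomal proteins the median of -0.188 lay below all of 10000 lists matched on exon length, GC content and expression, whose median was -0.052 and lowest value -0.159. Leaving out a sample moved the ribosomal median to between -0.259 (without sample 1 of Trps1 siRNA) and -0.122 (without sample 2), the latter above that lowest value. The matched lists do not carry the members' estimated correlation of 0.923. With an estimated correlation the call was lost (camera adjusted p = 0.715 with an estimated correlation), as was that of every list, on 2 residual degrees of freedom.

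Genes that fell with Trps1 siRNA were enriched for a short sequence in the 3' UTR, the kind of match through which an siRNA can lower other transcripts. Of 15561 heptamers, GAGTTGA went with the lowest fold changes (z = -17.28), and together with AGTTGAA it was held by 30.9% of 805 lowered genes against 16.5% of 9594 others. Between the 2 samples of a group its z was 0.51 and -1.48, against -14.81 or lower across groups. Other heptamers reached -4.79 and 4.82 between the Negative siRNA samples and -5.09 and 6.68 between the Trps1 siRNA samples. The values thus argue only against a difference of this size between any 2 libraries. The joined GAGTTGAA is held by 7 of 8 Trps1 coding transcripts, where chance gives 14% for a transcript of 9859 bases. These transcripts draw on the same sites, so their number is not one of separate matches. In Trps1-201 the sites lie in the coding sequence, at 50831471 to 50831478 and 50846777 to 50846784. A candidate explanation for part of the falls is therefore seed matching of the Trps1 siRNA, whose sequence the labels do not give, and siRNA and group are confounded. The 23 interferon genes without either heptamer still had a median of -0.327, which argues against sites in their own 3' UTRs for these genes. The 3 holders, Ddx58, Ifit2 and Oas2, had log2 fold changes of -0.746, -0.718 and -0.202, and for them a site stays open. Ccnd1 holds AGTTGAA and also stays open, since genes with that site differed by -0.071 on average against -0.48 for Ccnd1. Loss of Trps1 or indirect effects were not separated from seed matching.

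The same search gave TCGGAGA with the highest fold changes (z = 8.06), held with CGGAGAA by 12% of 677 raised genes against 3.6% of 9722 others, and of 8 Trps1 coding transcripts 0 hold the joined TCGGAGAA and 7 hold CGGAGAA. The z of TCGGAGA was -1.32 between the Negative siRNA samples, 0.37 between the Trps1 siRNA samples and 6.49 to 8.04 across groups. Another heptamer, TATATTT, reached 6.68 between the Trps1 siRNA samples, so a z of about this size also arose within a group. Of the 1652 changed genes, 805 lowered and 677 raised genes had a searched 3' UTR. Among genes with a searched 3' UTR, a leading heptamer of either direction was held by 410 changed genes and by 2161 of all 10399. Without these holders 619 higher and 623 lower genes were left, genes not searched included. With all holders left out and members not searched kept (for ribosomal proteins 32 of 42 were searched), 8 of 33 lists passed camera with the preset correlation, among them interferon response at -0.334 and ribosomal proteins at -0.193 (adjusted p = 3.24e-08 and 1.24e-09). For the full lists both calls were lost (adjusted p = 0.715 with an estimated correlation), and lists without holders were not run with an estimated correlation. Of the 10 lists that moved, 7 were among the 8, and DNA replication, YAP/TEAD targets and immediate early genes were not (camera adjusted p = 0.0983, 0.0538 and 0.152), while ATF4 targets passed at 0.00518 (0.0746 with all members).

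The rise of steroidogenic genes was set against a larger share of Leydig cells and against seed sites of the Negative siRNA. A larger share would raise Leydig markers by about a common factor, but 6 of 14, Prlr, Ptgds, Insl3, Vcam1, Star and Hsd11b1, had an upper 95% bound under the list's median of 0.43. That median is set largely by the steroidogenic genes themselves and the values were already known, so the count adds little. Outside the steroidogenesis list, Sult1e1 rose 2.37-fold. The upper bounds of Prlr, Ptgds, Insl3, Vcam1 and Hsd11b1 were 0.313, 0.165, 0.136, 0.037 and 0.025. The markers thus did not rise by a common factor, which argues against a larger share of Leydig cells as the whole cause. All 10 steroidogenic genes that rose were searched and 0 held a raised heptamer, which argues against seed sites of the Negative siRNA, as far as these heptamers mark them, in the members' own 3' UTRs. A response to lower Trps1 and an indirect effect of either siRNA stay open as hypotheses, since the design holds a single siRNA against Trps1.

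Negative siRNA sample 1 nearly lacked a small set of transcripts. In it 17 genes lay at least 2-fold under all other samples, against 1, 0 and 0 in the others, among them mt-Rnr1 (19.0 against 1020, 1040 and 1050 CPM), Fbl (2.14 against 74.9, 78.7 and 68.9 CPM) and Tsr2, and 0 of the 17 were called between the groups by edgeR. A lower nucleolar programme is argued against by 30 other nucleolar genes, whose median log2 difference was -0.021. Of 15 further genes named for rRNA, 0 lay 2-fold or more under the other samples, so not every gene named for rRNA was low. Their list left out the genes already seen to be low, so it cannot decide whether reads matching sequences annotated as rRNA were removed. Removal with a narrower set may remain and was not tested.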
